A study of Caenorhabditis elegans with 4 samples.

How the data were processed

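Total RNA was measured by bulk sequencing in whole Caenorhabditis elegans larvae collected at the first larval stage (L1) after synchronization. The 4 libraries comprised 2 from wild-type animals and 2 from dve-1(uf171) mutants, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, animals were kept at 25 degrees Celsius, and RNA was extracted with Trizol and cleaned on columns. Nothing in the labels states that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

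Per the submitters' processing notes, TopHat2 and Cufflinks were used with genome build ce11, and versions are not given in the sources used here. The deposited values are FPKM (fragments scaled by transcript length and by the number of mapped fragments), 1 value per RefSeq accession and library, for 52491 accessions. Whether reads that align to several places were divided, kept or dropped is not given in the sources used here, nor is strand.

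Accessions were matched without their version to a RefSeq gene table of assembly WBcel235, the same assembly as ce11, and FPKM were summed per gene. Of all accessions, 47645 matched, giving 41614 genes, and 4846 did not match and entered only 1 alternative. The unmatched accessions held 20.9% to 21.7% of summed FPKM in each library. The gene hsp-6 was among the names with no matched accession and was not analysed here. The 12 mitochondrial protein accessions were matched to mitochondrial genes. Transcript lengths and exon overlaps came from the Ensembl annotation of the same assembly, by symbol or, for 1098 genes, by locus tag, so that 99.9% of tested genes had a length.

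Total counts are not part of the FPKM table. Low values were therefore searched for steps of whole reads. Between the wild-type libraries, 365 of 1687 transcripts under 0.3 FPKM in the first library stood at 1 ratio, 0.9267 (tolerance 0.0002). Between the other pairs of libraries no more than 5 transcripts did. Fitting whole reads to transcripts of 400 to 4000 nt gave 23400000 and 21700000 fragments in the wild-type libraries and 18500000 and 19600000 in the mutant libraries. The fitted mean fragment length was 190 nt in both wild-type libraries and 250 and 260 nt in the mutant libraries, with resampling SDs of 3.66, 5.23, 9.52 and 54.2 nt. Of the transcripts fitted, 48.8%, 50.5%, 34.3% and 33.2% lay within 0.1 of a whole read, against 20% for evenly spread values without a fit. The fit was chosen to bring these same transcripts close to whole reads, so 20% is not the chance level after fitting. These depths are estimates, and no count test was run on them.

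Genes with a mean of at least 1 FPKM were tested, 15202 in all (12599 protein-coding and 2603 noncoding). The test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(FPKM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, mutant over wild type, which understates changes of low genes. Gene lists were tested with camera at a preset correlation of 0.01. Of 61 lists, 59 had at least 5 tested members. Median-ratio scaling, quantile normalization, pseudocounts of 0.1 and 0.01, other filters, other limma settings, a replicate block, stricter thresholds and each library left out were alternatives chosen before the data were examined, as were the lists, tests and rule for named genes. Alternatives on gene class, values of 0, shared reads, overlapping exons, transcript length and unmatched accessions were chosen after seeing the data. Genes were called equal in wild type when both values lay within 0.5% of those of another gene of the same family or clone name. A wider rule, which also takes protein-coding genes of identical values under any name, was added after the result of the first was seen.

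The rule named dve-1, ubl-5, atfs-1, hsp-6, hsp-60, unc-25, unc-47 and unc-30 in any case. It also named the 10 largest rises and 10 largest falls past the threshold at 5 FPKM or more with no overlap between groups, and the 5 most abundant genes past it each way. From each list described it named up to 3 risen and 3 fallen members, or the 2 most abundant where none passed. Other genes were named after their values were seen: eif-3.L, Y23H5A.8, ebp-1, glna-1, COX1, CYTB, ND3, rpl-41.2, rrn-3.1, the nspc genes, and hsp-16.2, hsp-16.41, hsp-70, dpy-13 and rol-6. Tested on simulated data of 15202 genes for this comparison, the limma step recovered 0% of 2-fold, 67.2% of 4-fold and 93.9% of 8-fold changes, with 5 false calls among 112, and camera called 0 of 40 unchanged lists. The simulated noise was independent between genes, and the unchanged lists were drawn at random. How much variances differ between genes of like level was set in advance and not estimated from these libraries. Reads shared between copies were not simulated. The recovered shares and false-call rates may therefore not hold for the real genes. This applies also to real lists, whose members can move together, and to genes listed near 0. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for matching, the other tests and plots.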

Results

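Gene expression was compared between wild-type and dve-1(uf171) mutant larvae at the first larval stage, with 2 whole-animal libraries of each genotype. DVE-1 is a homeodomain protein known for its part in the mitochondrial unfolded protein response. Summed FPKM were 2.39e+06 and 2.35e+06 in the wild-type libraries and 2.25e+06 and 2.05e+06 in the mutant libraries. Across tested genes, log2 values correlated at 0.858 between the wild-type libraries and 0.862 between the mutant libraries, against 0.808 to 0.836 between genotypes; genes are not independent replicates.

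The transcript of dve-1 itself (chromosome X, 427035 to 433812, WBcel235) was present in both genotypes. It was listed at 15.1 and 19.5 FPKM in wild type and at 23.4 and 25.5 FPKM in the mutant. The difference, a log2 fold change of 0.49 (SE 0.17), did not pass the limma threshold (adjusted p = 0.439). A mutant allele need not change the RNA level, so these values neither check nor contradict the labels.

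Mitochondrial genome-encoded transcripts were higher in the mutant. ND4, a subunit of respiratory complex I, rose from 411 ± 19.6 to 840 ± 14.7 FPKM (SD, n = 2), a log2 fold change of 1.03 (SE 0.09, limma adjusted p = 0.0459). COX1, a subunit of cytochrome c oxidase, stood at 1898 ± 17.4 FPKM in wild type and 3719 ± 223 in the mutant (SD, n = 2), and CYTB at 2760 ± 43.6 and 4846 ± 211, without passing alone (limma adjusted p = 0.0555 and 0.0678). Of the 12 mitochondrial genes, 1 passed over all genes and 8 passed adjusted over the list alone, all higher. In 9, both mutant values lay above both wild-type values. Chance gives 16.7% for a single gene, but genes measured in the same 4 libraries can move together, so this count is not a test. ND3 was listed at 0 in 3 libraries and at 453 FPKM in the second mutant library. The list passed camera with a median log2 fold change of 0.69 (adjusted p = 3.1e-06), against a median of 0.09 over all tested genes, but not with an estimated correlation (adjusted p = 0.966). With that setting 0 of the 59 lists reached an unadjusted camera p under 0.05, so a miss there does not set any list apart. The median of the mitochondrial list ranged from 0.57 to 0.78 with 1 library left out. ND4 missed the threshold with any of the 4 libraries left out (limma adjusted p = 0.121 to 0.192), under either other normalization and at a mean of at least 5 FPKM.

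**Figure D1:**
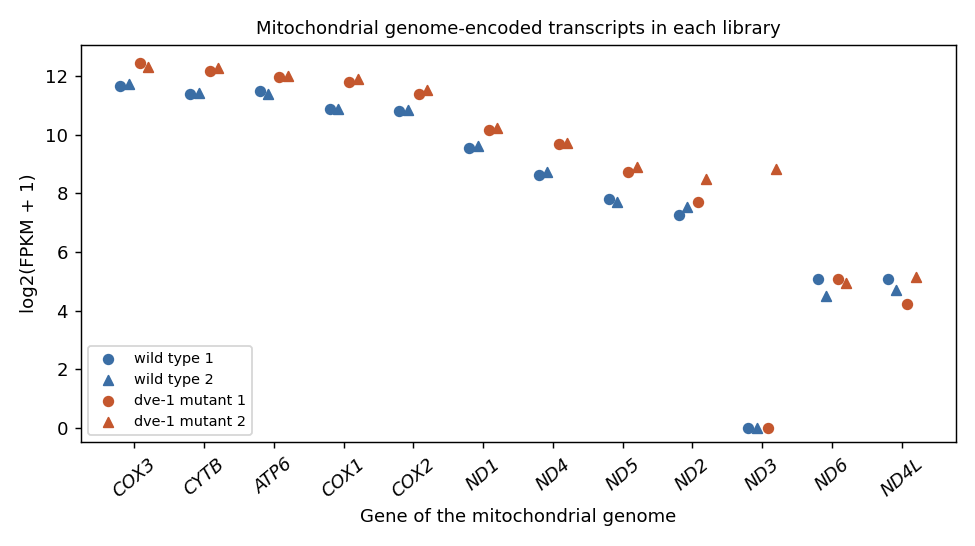
Level of each of the 12 mitochondrial genome-encoded transcripts, as log2(FPKM + 1), with 1 point per library, wild type in blue and dve-1 mutant in orange. Both mutant values lie above both wild-type values for 9 genes, and ND3 is listed at 0 in 3 libraries.

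Ribosomal protein genes were lower in the mutant. Among large-subunit genes rpl-8 fell from 8098 ± 656 to 2695 ± 40.04 FPKM (SD, n = 2; log2 fold change -1.58, SE 0.10, limma adjusted p = 0.0297). The paralogs rpl-37.1 and rpl-37.2 fell as well, from 9784 ± 216 to 3767 ± 320 FPKM and from 5502 ± 163 to 362 ± 42.7 FPKM (SD, n = 2; limma adjusted p = 0.0392 and 0.0074). Both are numbered copies, as is rpl-41.2 below, so reads shared between copies may affect their values. Exons of rpl-8 and rpl-37.1 also overlap another gene. Of 39 large-subunit genes tested, 3 fell over all genes and 6 adjusted over the list alone. In 36, both mutant values lay below both wild-type values, where chance gives 16.7% for a single gene. Ribosomal protein genes can move together: only 1 of 22 small-subunit genes was higher in the first than in the second wild-type library. The count of 36 is therefore not a test. Among 22 small-subunit genes 0 passed by limma, and 17 had both mutant values below; rps-20, the most abundant, stood at 15821 and 15514 FPKM. Median log2 fold changes were -0.33 and -0.21 (camera adjusted p = 2.36e-17 and 1.53e-07). Neither list passed with an estimated correlation (adjusted p = 0.966). The medians ranged from -0.36 to -0.29 (large subunit) and from -0.24 to -0.20 (small subunit) with 1 library left out. Under quantile normalization the large-subunit median shrank to -0.086 (camera adjusted p = 0.000396) and the small-subunit list missed (0.715, median -0.018). That method can remove a fall shared by the most abundant genes. Under median-ratio scaling both lists passed, with medians of -0.433 and -0.311 (camera adjusted p = 1.76e-19 and 8.23e-10). With 1 library left out, rpl-8 and rpl-37.1 passed in no case (limma adjusted p = 0.155 to 0.289 and 0.221 to 0.33), and rpl-37.2 missed without either wild-type library (up to 0.0797). The most abundant transcript, rpl-41.2, took 9.21% and 10.3% of summed FPKM in wild type and 5.70% and 5.51% in the mutant (limma adjusted p = 0.0879).

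The proteasome degrades ubiquitin-tagged proteins. Its list, made of subunits and also skn-1 and aip-1, had a median log2 fold change of -0.13 over 33 genes (camera adjusted p = 0.000595). The 66 mitochondrial ribosomal proteins had one of -0.14 (0.00242). Both lists missed with an estimated correlation (0.966). No member of either list passed alone; pbs-1 stood at 209 ± 25.6 and 155 ± 15.5 FPKM and mrpl-36 at 336 ± 48.11 and 305 ± 68.8 FPKM (SD, n = 2). With 1 library left out the proteasome median ranged from -0.24 to -0.037, and the list missed without the second wild-type or the first mutant library (0.0731 and 0.0796). The mitochondrial ribosomal median ranged from -0.20 to -0.014, and that list missed without the first wild-type or the first mutant library (0.595 and 0.3).

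The mitochondrial unfolded protein response list did not pass. Its 20 tested genes, which did not include hsp-6, had a median log2 fold change of 0.01 (camera adjusted p = 0.72). The mean and median of the list were above 0 while the test pointed down. The chaperonin gene hsp-60 stood at 242 ± 63.3 and 241 ± 60.1 FPKM, atfs-1, which encodes a transcription factor of this response, at 124 ± 21.9 and 154 ± 13.3 FPKM, and ubl-5, which encodes a ubiquitin-like partner of DVE-1, at 242 ± 14.5 and 181.5 ± 19.9 FPKM (SD, n = 2; limma adjusted p = 0.999, 0.577 and 0.397). Nuclear-encoded respiratory chain genes (39 tested, median -0.07, camera adjusted p = 0.202), ubiquitin conjugation and ligase genes (59 tested, median 0.08, 0.768) and deubiquitinases (19 tested, median -0.01, 0.552) did not pass either. The respiratory chain list did pass, as lower, under median-ratio scaling (0.037, median -0.17) and without the second mutant library (0.000835, median -0.14).

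Some neuronal and receptor lists tested higher in the mutant and others did not pass. GABAergic genes did not pass (21 tested, median 0.11, camera adjusted p = 0.547): unc-25, which encodes the GABA-synthesizing enzyme, stood at 51.3 ± 0.416 and 60.4 ± 1.21 FPKM, the vesicular transporter gene unc-47 at 7.25 ± 0.627 and 11.8 ± 1.45, and the homeobox gene unc-30 at 14.7 ± 0.355 and 11.8 ± 3.85 (SD, n = 2; limma adjusted p = 0.489, 0.326 and 0.627). Glutamatergic and monoaminergic genes (23 tested, median 0.24, camera adjusted p = 0.0329), motor-circuit receptor and associated genes (25 tested, median 0.19, 0.049) and neuropeptide-like proteins (66 tested, median 0.20, 0.0306) passed, with 0 members past limma alone. Of their members, lev-10 stood at 51.1 and 67.1 FPKM and nlp-40 at 2903 and 3103 FPKM. Nuclear hormone receptors (189 tested, median 0.24, 0.000433) and the chemoreceptor families str (23 tested, median 0.46, 0.0366) and srh (27 tested, median 0.41, 0.0366) passed too. Cholinergic, synaptic vesicle, ciliated sensory, FMRFamide-like and sri lists did not (0.202, 0.444, 0.164, 0.13 and 0.0517), though sri passed under 13 of 22 alternatives. The 6 that passed all missed with an estimated correlation (adjusted p = 0.966). Motor-circuit receptors passed under 4 of 23 alternatives, glutamatergic and monoaminergic genes under 13 and neuropeptide-like proteins under 12; without the first mutant library all 3 missed (0.427, 0.127 and 0.969, the last with a median of 0.030), as did nuclear hormone receptors (0.0683). Without the low-value filter str and srh missed (168 and 196 tested, medians 0.12 and 0.092, adjusted p = 0.0646 and 0.147).

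**Figure D2:**
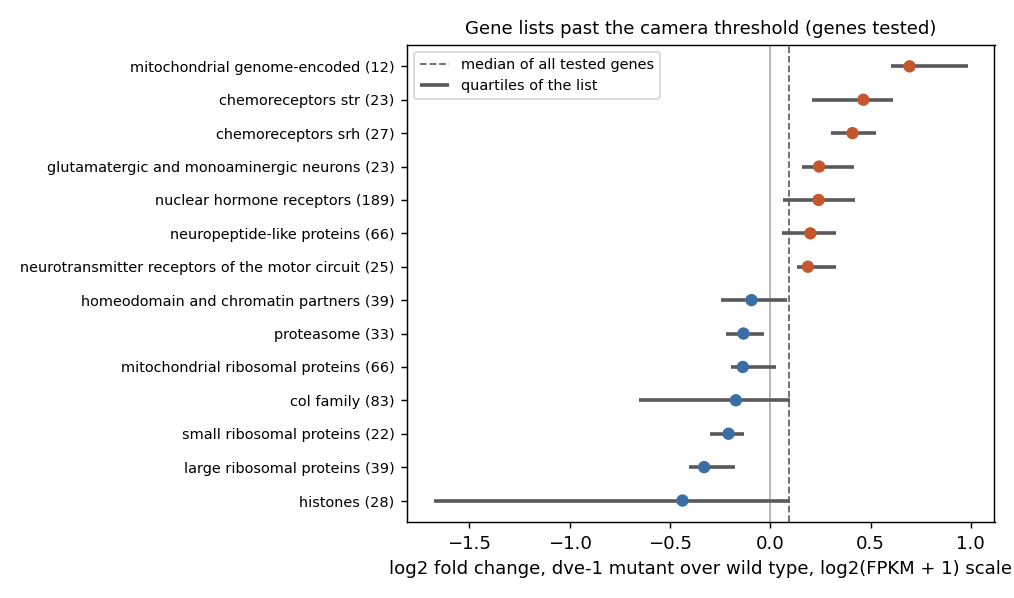
Median log2 fold change (point) and quartiles (line) of each of the 14 gene lists past the camera threshold, with the number of genes tested in brackets; orange lists tested higher and blue lower in the mutant, and the dashed line is the median of all tested genes, 0.09. Mitochondrial genome-encoded genes have the highest median, 0.69.

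Genes of the cuticle varied within each genotype. The cuticle gene cut-2 was listed at 192 and 10.05 FPKM in the wild-type libraries and at 19.4 and 102 FPKM in the mutant libraries, and the collagen gene sqt-3 at 136 and 3.36 and at 8.59 and 53.8 FPKM. Of 43 tested cuticle collagen and moulting genes, 39 were higher in the first than in the second wild-type library and 35 were higher in the second than in the first mutant library. The list did not pass (median -0.03, camera adjusted p = 0.947), but its median was 1.1 without the first wild-type library, where it passed as higher (0.021), and -1.17 without the second (0.0843). The col family passed with a median of -0.17 over 83 genes (adjusted p = 2.39e-06, 0.966 with an estimated correlation), and 5 members fell and 0 rose; it missed without the first wild-type library (0.232). Of these, col-169 fell from 492 ± 6.90 to 34.1 ± 8.25 FPKM (SD, n = 2; limma adjusted p = 0.02), but missed without either wild-type library (0.202 and 0.209). The copies col-3 and col-117 had equal wild-type values, 1750 and 1904 FPKM, and stood at 0.108 and 0.226 and at 0.0721 and 0.264 FPKM in the mutant.

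Over all genes, 252 changed by limma, 46 higher and 206 lower in the mutant, of 15202 tested. Most of these were near 0 in 1 genotype: 41 of the 46 lay under 0.5 FPKM in both wild-type libraries and 167 of the 206 under 0.5 FPKM in both mutant libraries. Many were also short: 39 of the 46 and 116 of the 206 had an annotated transcript of at most 250 nt, against 16.9% of tested genes. Of the higher genes 37 were noncoding, and of the lower genes 105. These 105 included 15 of 18 tested rRNA and 14 of 65 snRNA genes, all listed at 0 in both mutant libraries, and 13 and 12 of them had wild-type values equal to another gene; the rRNA gene rrn-3.1 stood at 104.4 and 192 FPKM in wild type and at 138 and 184 in the mutant. The muscle and cytoskeletal actin gene act-1, a member of a family of near-identical copies, was listed at 1982 and 2126 FPKM in wild type and at 0.131 and 0.177 FPKM in the mutant. Genes that every cell uses were among them: eif-3.L, which encodes a translation initiation factor subunit, was listed at 76.6 and 78.7 FPKM in wild type and at 0 in both mutant libraries, and nola-3 at 489 and 584 FPKM and at 0. Values of 0 are therefore given only as listed. The largest differences included F46A8.7, listed at 6889 and 11726 FPKM in wild type and at 0 in the mutant, and dct-16, listed at 0 in wild type and at 194 and 272 FPKM in the mutant.

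**Figure D3:**
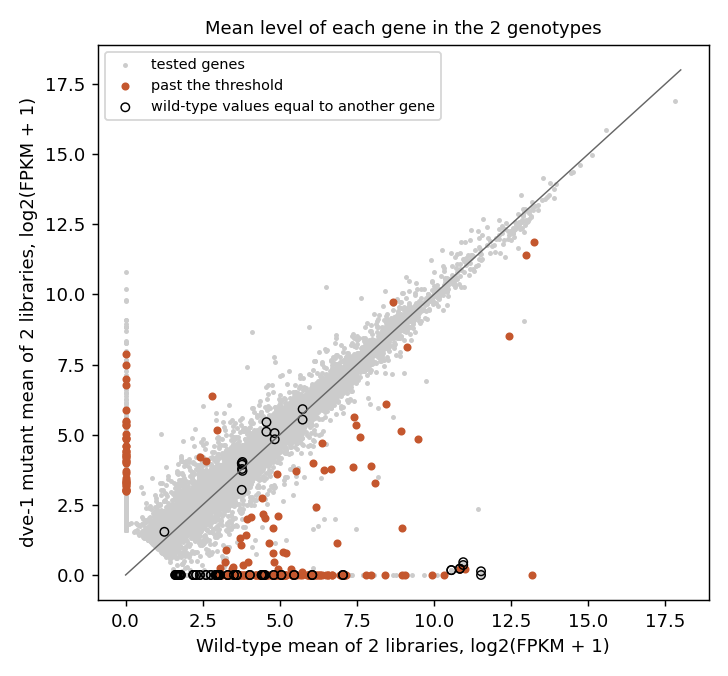
Mean log2(FPKM + 1) of each tested gene in wild type (horizontal) and in the dve-1 mutant (vertical), each over 2 libraries; orange points passed the limma threshold, and circles mark genes whose wild-type values equal those of another gene. Of the 206 lower genes, 167 lie at the bottom edge, under 0.5 FPKM in both mutant libraries.

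Among genes at 0.5 FPKM or more in at least 1 library of each genotype, mtl-2, a metallothionein gene of the intestine, fell from 557 ± 5.42 to 278 ± 9.17 FPKM (SD, n = 2; 2-fold, limma adjusted p = 0.0458). The microtubule end-binding protein gene ebp-1 fell from 28.9 ± 1.21 to 11.1 ± 0.354 FPKM and the glutaminase gene glna-1 from 14.4 ± 1.23 to 3.02 ± 0.0621 FPKM (SD, n = 2; limma adjusted p = 0.0444 and 0.0359). Y23H5A.8 rose from 6.73 ± 0.675 to 34.9 ± 4.05 FPKM (SD, n = 2; limma adjusted p = 0.0326). The neighbouring catalase genes ctl-1 and ctl-3 were listed at 34.5 and 36.4 and at 32.3 and 33.7 FPKM in wild type, and at 0.437 and 1.00 and at 0.469 and 1.07 FPKM in the mutant (limma adjusted p = 0.0177 and 0.0198); they are close copies, so their values are uncertain. With 1 library left out none of these genes passed in any case: mtl-2 (limma adjusted p = 0.0953 to 0.157), ebp-1 (0.173 to 0.219), glna-1 (0.13 to 0.256), Y23H5A.8 (0.179 to 0.199), ctl-1 (0.0527 to 0.178) and ctl-3 (0.0546 to 0.193). The count of changed genes rose to 750 and 767 without the first or second wild-type library, and was 369 and 467 without the first or second mutant library. Of these calls, 90% and 91% were higher in the mutant in the last 2 cases, against 18.3% with all libraries.

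Histone genes passed with a median of -0.44 over 28 genes (camera adjusted p = 0.000433, 0.966 with an estimated correlation). No member passed alone, and the most abundant, his-72, stood at 922 ± 4.08 and 1008 ± 68.5 FPKM (SD, n = 2). The list missed at a mean of at least 5 FPKM (7 genes, median -0.011, adjusted p = 0.47). It also missed in alternatives chosen after seeing the data: among genes above 0 in all 4 libraries (18 genes, median 0.014, 0.195), among protein-coding genes of at least 500 nt (5 genes, median 0.13, 0.418) and without genes of equal wild-type values (22 genes, median -0.11, 0.054, and 0.0532 by the wider rule). Homeodomain and chromatin partner genes passed with a median of -0.09 over 39 genes (camera adjusted p = 0.0366, and 0.966 with an estimated correlation). The 1 member past limma, hmg-1.2, was listed at 15.1 and 20.3 FPKM in wild type and at 0 in the mutant. This gene missed the limma threshold at a mean of at least 5 FPKM. That list missed at a mean of at least 5 FPKM (0.0635) and without the second wild-type or the first mutant library (0.826 and 0.236).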

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

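The tests on genes of equal wild-type values, short transcripts, the whole scale, library handling, ribosomal gene copies and length alone were chosen after the result was seen, as was the limit on how closely random lists had to match. The 2 tests with lists matched on mean FPKM were chosen before. Accessions matched to no gene lay outside the comparisons of genes. When they were tested with the genes, by limma, 18 of 2944 were higher in the mutant and 65 lower.

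Genes near 0 in the mutant: 524 genes had a wild-type mean of at least 5 FPKM and lay under 0.5 FPKM in both mutant libraries, and 312 showed the reverse. A candidate explanation is that reads shared between copies were left out of the mutant values alone: 82.3% of 79 genes of equal wild-type values lay under 0.5 FPKM in both mutant libraries, against 4.38% of 10473 other genes, and 0 of 12 genes of equal mutant values did so in wild type. The wider rule, added after this result was seen, gave 81.4% of 97 genes. For the rest, short transcripts may be the source, since 85.2% had an annotated transcript of at most 250 nt, against 16.9% of tested genes. An effect of the dve-1 genotype on these genes stays open and was not tested.

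Higher mitochondrial genome-encoded transcripts: a change of the whole scale is argued against, because the median log2 fold change of all tested genes was 0.0949 and the lower quartile of the mitochondrial genes was 0.60. Abundance is argued against too, as 0% of 10000 random lists of nuclear genes matched on mean FPKM had a median as high, the random lists having a median of -0.04. Different library preparation or quantification of the 2 genotypes and an effect of the genotype cannot be told apart, since any such difference would coincide with genotype. The test of it could not decide: 0 of 4 pairs of a wild-type and a mutant library shared a step size of low values, but the 2 mutant libraries shared none either (5 of 1345 transcripts at the commonest ratio). Fitted fragments were longer in the first mutant library (250 nt, SD 9.52) than in the wild-type libraries (190 nt, SD 3.66 and 5.23), which would go with different preparation. The fit for the second mutant library (260 nt, SD 54.2) was too uncertain to tell. These resampling SDs cover the fit within a library and not the spread between libraries, so the fragment lengths cannot decide it.

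Lower ribosomal protein transcripts: transcript length alone is argued against, since 0% of 10000 random lists matched on length had a median as low as that of the 61 genes, -0.28. Reads shared between gene copies do not account for the whole pattern, because 55 genes without a numbered copy still had a median of -0.24, with an upper quartile of -0.15. Abundance and an effect of the genotype cannot be told apart. Lists matched on length and mean FPKM also gave 0%, but their genes lay 1.525 lower in log2 mean FPKM, because only 8 other protein-coding genes lay above the lower quartile of ribosomal gene abundance. Those 8 had a median of -0.066 (quartiles -0.17 and 0.035), nearer 0 than the ribosomal genes, but were too few to decide. Under quantile normalization the medians shrank to -0.086 (large subunit) and -0.018 (small subunit), and under median-ratio scaling they were -0.433 and -0.311. Quantile normalization gives all libraries the same values at each rank, so it can remove a fall shared by the most abundant genes. The shrinkage therefore cannot decide. Quantification that differed by genotype and an effect of the genotype both stay open and were not tested for these genes.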

How the results depend on the processing

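Of the alternatives below, those on gene class, values of 0, shared reads, overlaps, length and unmatched accessions were chosen after seeing the data. The log2 fold change of dve-1 stayed above 0 and short of the threshold under all 23 alternatives (0.31 to 0.66, adjusted p 0.383 to 0.677). The count of 252 changed genes became 105 at a mean of at least 5 FPKM, 391 without the intensity trend and 58 at an adjusted p under 0.01. It became 165 for protein-coding genes, 102 for those of at least 500 nt, 54 for genes above 0 in all 4 libraries, 157 without genes of equal wild-type values by the wider rule (170 by the first rule), and 24 for all these limits by the first rule together with no overlapping exons. The cause of these shifts was not tested beyond the fewer genes tested. Leaving out 1 library gave 369 to 767 genes; 84.8% to 90.4% of those calls lay under 0.5 FPKM in both libraries of the genotype that kept 2, whose spread alone then set the test. With the replicate number as a block, limma called 0 genes (1166 at an unadjusted p under 0.05) and camera 10 lists; deviations of same-numbered libraries correlated at -0.0562, so the numbers gave no sign of pairing. Of 59 lists, 14 passed with all data, 8 at a mean of at least 5 FPKM, 0 with an estimated correlation (0 at an unadjusted p under 0.05) and 0 by fry (6 at an unadjusted p under 0.05, 5 of them among the 14). With 1 library left out 10 to 18 passed, of which 7 to 12 were among the 14. Over the named genes, 167 of 3283 values missed a threshold passed with all data, 13 newly passed and 0 reversed. The 3283 values include those of named genes that did not pass with all data and so could not miss. Among genes that did pass, the share of missed values is therefore higher than 167 of 3283, and it was not computed. These counts are thus no measure of how stable the calls of single genes are. A change of sign was counted as reversed only where the gene passed the threshold in either fit. Sign changes of genes short of it in both fits were counted as unchanged. Random lists and the authors' test, planned for a table of group means, were not run as alternatives. Depth is known only as an estimate, and a 2-fold change was recovered in 0% of simulated genes.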

Other observations

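Some heat shock genes varied within each genotype: 16 of 19 on the cytosolic list were higher in the first than in the second wild-type library, and 12 of 19 were higher in the second than in the first mutant library. The genes hsp-16.2, hsp-16.41 and hsp-70 were picked after their values were seen. The small heat shock gene hsp-16.2 was listed at 749.6 and 77.2 FPKM in wild type and at 160.5 and 386.0 FPKM in the mutant, hsp-16.41 at 1173 and 83.8 and at 370.3 and 987.7 FPKM, and the inducible chaperone gene hsp-70 at 55.9 and 3.06 and at 15.4 and 42.4 FPKM. The first wild-type and the second mutant library were thus the higher of each pair, as they were for the cuticle genes dpy-13 (131.5 and 2.48, then 3.84 and 49.9 FPKM) and rol-6 (47.8 and 0.986, then 2.23 and 20.01 FPKM). The cytosolic heat shock list had a median log2 fold change of 0.05 and a mean of -3.01 over 19 genes, with 0 past the threshold over all genes and 6 lower adjusted over the list alone (camera adjusted p = 0.0689, pointing down). That list passed as lower without the second wild-type library (0.00757, median -0.52) but not without the first (0.553, median 0.29). Its copies hsp-16.1 and hsp-16.11, equal in wild type, were listed at 5190 and 699.8 and at 5190 and 699.95 FPKM there, and at 0 or 0.192 FPKM in the mutant. The pairs hsp-16.48 and hsp-16.49, and F44E5.4 and F44E5.5, were also equal in wild type. They were listed at 487.3 FPKM or more there and at no more than 0.744 FPKM in the mutant. The list's mean of -3.01 thus rests largely on copies of equal wild-type values.

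The engulfment receptor gene ced-1 was listed at 794.5 FPKM in the first mutant library and at 16.45, 16.18 and 18.7 FPKM in the others. The nspc genes, a nematode-specific peptide family, were picked after their values were seen and given no list test; 10 of 18 tested passed the threshold, all lower in the mutant, and 8 did not; nspc-20 stood at 347 ± 2.24 and 67.3 ± 9.84 FPKM and nspc-19 at 191 ± 6.23 and 28.9 ± 1.32 FPKM (SD, n = 2; limma adjusted p = 0.0267 and 0.0105); nspc-20 missed without either wild-type library (up to 0.213). Family members are close copies, so these values are uncertain.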
